A study of Mus musculus with 21 samples.

How the data were processed

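Messenger RNA was measured by RNA sequencing in mouse pancreatic tumour cells of the clones 6694c2 and 6419c5, which had been implanted subcutaneously in C57BL/6 mice and sorted back from the tumours 3 weeks later, per the labels. Each clone was represented by its parental line, called WT here because its titles carry the clone name alone, and by 2 lines labelled EPHA2-KO. The 21 libraries formed 6 groups, with 4 libraries in each group of 6694c2 and 3 in each group of 6419c5. The table letters the knockout lines A and B and the labels number them 1 and 2, and no source ties a letter to a number. The lines are therefore called KOA and KOB, and no comparison of KO with WT depends on which is which. The labels do not say how EPHA2 was edited, and they do not say that the libraries of a line came from separate animals.

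The deposited values were gene-level TPM, a measure of relative transcript abundance, made by the authors with Salmon against the mouse build mm10, per the labels. The Salmon version, the transcript annotation and the step from transcripts to genes were not stated. The table held 24623 gene symbols, and every library added up to 1000000 TPM over them. TPM keeps no record of the number of reads, so the depth per library is unknown and no counting interval could be given. The only precision available was the spread between libraries. Between 12437 and 13316 genes reached 1 TPM per library, and between 6798 and 7478 genes were listed at 0. Pearson's r of log2(TPM + 1) across genes between libraries of a group ran from 0.961 to 0.991. The table held none of the 13 mitochondrially encoded genes. Positions on mm10 were taken from the RefSeq gene table for 24523 symbols, 564 of them by a synonym.

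Values were analysed as log2(TPM + 1), a pseudocount of 1, in R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes with at least 1 TPM in at least 3 libraries were tested, which left 14337. One limma model (lmFit, contrasts, eBayes with trend) was fitted to all 21 libraries with a mean for each of the 6 groups. It had 15 residual degrees of freedom and 3.12 prior degrees of freedom. The KO effect of a clone was the mean of KOA and KOB less WT. The effect in 6694c2, the effect in 6419c5, the mean of both and their difference (6694c2 less 6419c5) were the main contrasts. KOA and KOB were also compared with WT and with each other in each clone, and the WT lines of the clones were compared. Limma's moderated test was two-sided, p values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Errors of fold changes are standard errors from limma, and errors of TPM are standard deviations between libraries. A p value measures the spread between libraries of a line. With 1 WT line and 2 KO lines per clone, it does not by itself set the knockout apart from other differences between lines.

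The comparisons, the tests, 31 gene lists, the rule for naming genes and the other settings to be tried were fixed before the data were examined. Of the lists, 29 had at least 3 tested genes and were compared with all other genes by camera in limma, with the preset correlation of 0.01 between genes, adjusted over the lists of a contrast. Camera was repeated with a correlation estimated from the data. Fry was run as well, whose p value tests whether the genes of a list move one way on balance and does not compare them with other genes. List members were also counted with p values adjusted over the list alone. A list score was the mean log2(TPM + 1) of the tested members in a library, and KO and WT scores were compared within each clone by an exact two-sided permutation test, adjusted over the 29 lists. The same exact test was run for Epha2 and Ptgs2. Genes were named by a rule. For each main contrast it took the 12 largest log2 fold changes in each direction among called genes with a group mean of at least 2 TPM and, for a KO effect, the same sign in KOA and KOB. It took 6 in each direction for KOA against KOB and for WT against WT. Gene models without a name were passed over. Whatever their values, it also included a fixed set of genes, among them Epha2, Ptgs2, Tgfb1, Cd274, Cxcl1, Csf2, Csf3, Trp53, Myc and Cdkn2a, and up to 4 members of each list with the smallest p in a main contrast.

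Shared change between clones was measured by Pearson's r and Spearman's rho across genes, which are not independent replicates, and by the genes called in both beside the number expected from the 2 counts alone. KOA and KOB of a clone share their WT libraries, so their correlation was set beside 100 simulations of unchanged groups against the same WT libraries, and in 6694c2 beside WT libraries split 2 and 2. Chromosome medians of log2 fold changes were compared with 1000 shuffles of the genes. The procedure was tested on simulated data with 200 changed genes among 14337. It found 61.2% of the genes changed by 0.5 (log2) and 91.0% of those changed by 1 for the KO effect in 6694c2, and 43.3% and 88.1% in 6419c5. Between 3.11% and 5.49% of the calls were false. A list shifted by 0.5 passed camera there, and 0 of 30 unshifted lists passed. Simulated genes varied independently of each other, and the simulated lines had no other differences. The simulation therefore does not test camera on correlated genes, and correlations estimated from the data reached 0.958 (MHC class II).

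The other settings were pseudocounts of 0.1 and 5, no filter, a filter at 5 TPM, median-of-ratios size factors, quantile normalization, rescaling without ribosomal protein genes and hemoglobins, eBayes without trend, arrayWeights, a replicate block, KO lines pooled, the line as a random effect (duplicateCorrelation), the macrophage score as a covariate, each clone fitted alone, WT libraries split, and each library left out in turn. No library was left out of the main comparisons. Mitochondrially encoded genes and the list of Xist and Y-linked genes, of which 1 was tested, were not tested as lists.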

Results

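The data were 21 RNA sequencing libraries of tumour cells from 2 clones of mouse pancreatic cancer. Clone 6694c2 had 12 libraries, 4 of the WT line and 4 of each of its lines labelled EPHA2-KO, KOA and KOB. Clone 6419c5 had 9 libraries, 3 of each of its lines. EPHA2 is a receptor tyrosine kinase of the Eph family, whose ligands are ephrins, and is encoded by Epha2. The series compares the parental line of each clone with lines of that clone labelled EPHA2-KO. The values were TPM, so the number of reads behind a library is unknown. The first 4 principal components of the tested genes held 34.5%, 23.4%, 10.6% and 7.14% of the variance.

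The first comparison asked whether the targeted gene was lower in the libraries labelled EPHA2-KO. Epha2 lies on chromosome 4 from 141301221 to 141329384 (mm10). In 6694c2 it measured 244.7 ± 5.11 TPM in WT, 114.9 ± 18.3 in KOA and 97.8 ± 11.4 in KOB (SD, n = 4 each). The KO effect was −1.21 ± 0.09 (log2, SE, adjusted p 1.5e-08), and 8 of 8 KO libraries lay below the lowest WT library (exact two-sided permutation p 0.00202, the smallest the design allows). In 6419c5 it measured 176.2 ± 13.5 TPM in WT, 150.5 ± 6.05 in KOA and 197.1 ± 25.7 in KOB (SD, n = 3 each). There the KO effect was −0.03 ± 0.10 (adjusted p 0.819, exact permutation p 0.833). The KO lines of 6419c5 went opposite ways, and neither was called. All 3 KOA libraries lay below the lowest WT library (−0.22, adjusted p 0.173), and 2 of 3 KOB libraries lay above the highest (0.16, adjusted p 0.312). The effect in 6419c5 turned to 0.02 without WT library 3 (adjusted p 0.906) and to 0.02 without KOB library 1 (adjusted p 0.909). It ran from −0.16 to 0.05 over all alternatives. The difference between the clones was −1.18 ± 0.14 (adjusted p 6.79e-06). Whole-gene TPM does not measure the protein, and it does not show an edit that leaves the transcript in place.

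**Figure D1:**
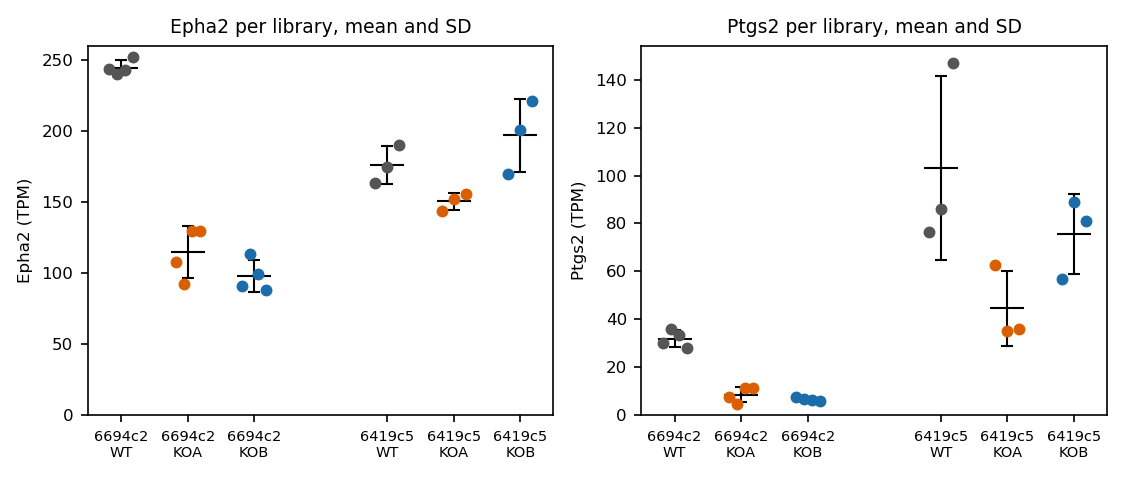
TPM of Epha2 and of Ptgs2 in each library, by clone and line, with points for libraries and bars for the group mean and SD. Epha2 in 6419c5 stayed between 143.8 and 220.8 TPM in the KO libraries, while in 6694c2 every KO library lay below every WT library.

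Ptgs2, the gene of cyclooxygenase 2 (chromosome 1, 150100031 to 150108234), was lower in the KO libraries of 6694c2. It measured 31.9 ± 3.66 TPM in WT, 8.56 ± 3.31 in KOA and 6.49 ± 0.608 in KOB (SD, n = 4 each), a change of −1.99 ± 0.22 (adjusted p 1.26e-06, exact permutation p 0.00202), with 8 of 8 KO libraries below the lowest WT library. In 6419c5 it measured 103.1 ± 38.4 TPM in WT, 44.5 ± 15.6 in KOA and 75.6 ± 16.6 in KOB (SD, n = 3 each). The change there was −0.80 ± 0.25 (adjusted p 0.0158) by limma, and the exact permutation test gave 0.107 with 4 of 6 KO libraries below WT. By line it was −1.19 in KOA (adjusted p 0.00395) and −0.41 in KOB (adjusted p 0.269). The call in 6419c5 was lost without WT library 3 (−0.51, adjusted p 0.143) and without the libraries of high Mir6236 (−0.51 ± 0.27, adjusted p 0.154). The libraries of high Mir6236 were 6694c2 KOB library 4 and the same 6419c5 WT library 3. Rescaling without Mir6236 kept the call (−0.83 ± 0.26, adjusted p 0.0137). The call was also lost with KO lines pooled (−0.80 ± 0.29, adjusted p 0.0508) and with the macrophage score as a covariate (−0.70 ± 0.28, adjusted p 0.0606). The macrophage list had a median of −1.73 in the same clone, with 8 of 29 markers called lower and 2 higher. Its score did not pass the exact permutation test there (p 0.179, adjusted 0.273). With the line as a random effect Ptgs2 was called in neither clone (adjusted p 0.0749 in 6694c2 and 0.506 in 6419c5) nor for the difference (adjusted p 0.827), and it was called for the mean (adjusted p 0.0309). The difference between the clones was −1.20 ± 0.33 (adjusted p 0.0113) by the model of groups, and the mean was −1.39 (adjusted p 1.81e-06).

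Tgfb1 (chromosome 7, 25687002 to 25705077) moved in opposite directions in the KO lines of 6694c2, by 0.52 in KOA (adjusted p 0.0093) and by −1.68 in KOB (adjusted p 1.31e-08). In 6419c5 it did not pass (−0.01, adjusted p 0.946). The difference between the clones (−0.57, adjusted p 0.022) was lost without 6419c5 WT library 1 (−0.47, adjusted p 0.0759) or WT library 2 (−0.53, adjusted p 0.0569). Cd274, which encodes PD-L1 (chromosome 19, 29362107 to 29388095), was higher in the KO libraries by 0.74 ± 0.24 in 6694c2 (adjusted p 0.0221) and by 1.14 ± 0.28 in 6419c5 (adjusted p 0.00333). Its means were 3.13 TPM in WT, 6.80 in KOA and 5.15 in KOB of 6694c2, and 4.11, 11.4 and 10.5 TPM in 6419c5. The call in 6694c2 was lost without WT library 1 (adjusted p 0.0639), WT library 3 (0.0538) or WT library 4 (0.0712).

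Csf2 fell by 1.87 in 6694c2 (adjusted p 0.00265), with −0.90 in KOA (adjusted p 0.225) and −2.85 in KOB (adjusted p 1.43e-04), and did not pass in 6419c5 (−1.19, adjusted p 0.0706), where it passed without 6694c2 KOA library 2 (adjusted p 0.00553). In 6694c2 KOA it ranged from 3.58 to 45.5 TPM. Csf3 was lower in 6694c2 (−0.60, adjusted p 0.0395) and higher in 6419c5 (0.81, adjusted p 0.0155), a difference of −1.41 (adjusted p 0.00421). The decrease in 6694c2 lay in KOB (−1.11, adjusted p 0.00139) and not in KOA (−0.09, adjusted p 0.833), with means of 1.62 TPM in WT, 1.59 in KOA and 0.194 in KOB. In 6419c5 Csf3 measured 0.50, 2.11 and 1.19 TPM, and KOB there was not called (adjusted p 0.132). Its call in 6694c2 was lost without WT library 1 (0.0623), 2 (0.146) or 3 (0.112) or KOB library 2 (0.0597), 3 (0.0578) or 4 (0.0551). Its call in 6419c5 was lost without WT library 2 (0.0675) or 3 (0.0676). Myc was not called in 6694c2 (−0.07, adjusted p 0.621) and was higher in 6419c5 (0.50, adjusted p 0.00146), a difference of −0.57 (adjusted p 0.00766). Trp53 was not called in 6694c2 (0.19, adjusted p 0.0939), where it passed without KOB library 4 (0.26, adjusted p 7.3e-04), or in 6419c5 (0.05, adjusted p 0.741). Cxcl1 was not called in 6694c2 (−0.70, adjusted p 0.281) or in 6419c5 (−0.73, adjusted p 0.321). Cdkn2a was listed at 0 in all 4 WT libraries of 6694c2 and measured 803.4 ± 84.6 TPM in WT of 6419c5 (SD, n = 3), where the KO effect of 0.05 was not called (adjusted p 0.803).

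The main comparison asked which genes differed between KO and WT in each clone. In 6694c2 limma called 5361 genes, 3429 higher and 1932 lower in KO. In 6419c5 it called 5942 genes, 3796 higher and 2146 lower. The mean of both clones had 7010 calls, 4625 higher and 2385 lower. The excess of higher genes rested on the scale of the values. With median-of-ratios size factors the calls were 2710 higher and 3022 lower in 6694c2, 3172 and 3117 in 6419c5, and 3538 and 3728 for the mean. Quantile normalization gave 2616 higher and 2907 lower in 6694c2, and 3217 and 3284 in 6419c5. Changes of at least 1 on the log2 scale were called in 783 genes of 6694c2, 478 higher and 305 lower, and in 1089 genes of 6419c5, 608 higher and 481 lower. With the line as a random effect, which counts the spread between KO lines as error, 130 genes were called in 6694c2, 589 in 6419c5 and 819 for the mean.

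The KO effects of the clones, which share no library, correlated across genes with r 0.404 and rho 0.344. Genes called higher in both clones numbered 1595, against 908 from the 2 counts alone. Genes called lower in both numbered 640, against 289, and 523 were called in opposite directions, against 1025. Genes called higher in both lines of 6694c2 (1194) and in both lines of 6419c5 (2141) had 437 in common, against 178 from these counts alone. Genes called lower in both lines of each clone had 141 in common, against 47.6.

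**Figure D2:**
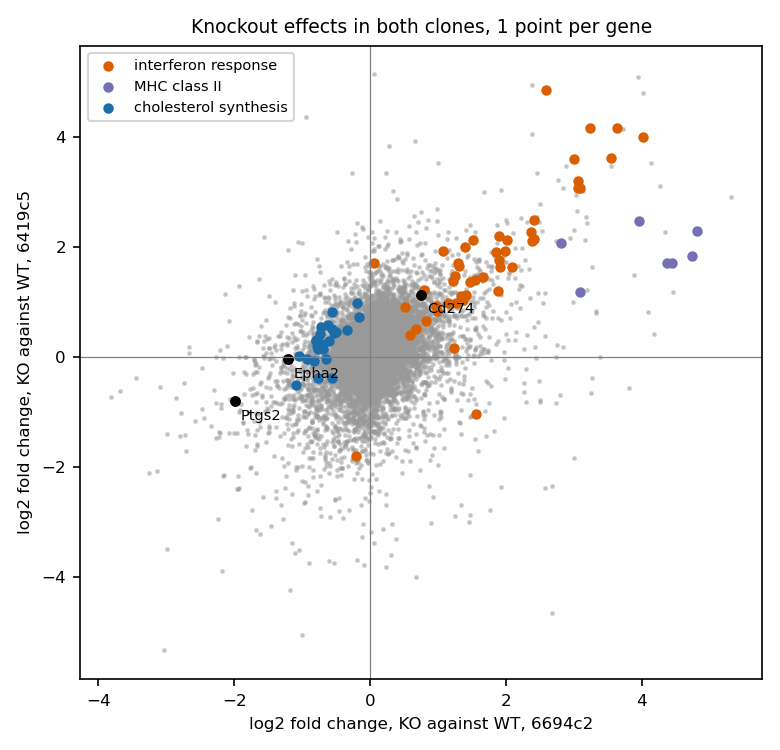
Log2 fold change of KO against WT for each tested gene, in 6694c2 on the x axis and in 6419c5 on the y axis, with the interferon response, MHC class II and cholesterol synthesis lists coloured and Epha2, Ptgs2 and Cd274 labelled. Most interferon response genes were higher in both clones, and most cholesterol synthesis genes lay to the left of 0, with a median of −0.70 in 6694c2 and 0.30 in 6419c5.

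The largest increases included genes of the interferon response and of antigen presentation. In the mean of both clones the largest among well-identified genes were Ubd (4.51 ± 0.29, adjusted p 1.56e-09; chromosome 17, 37193892 to 37196101) and Cxcl9 (4.41 ± 0.29, adjusted p 2.04e-09; chromosome 5, 92321331 to 92328079). Cxcl9 measured 1.22 TPM in WT, 29.0 in KOA and 43.5 in KOB of 6694c2, and 2.63, 63.6 and 158.2 TPM in 6419c5. Psmb8 (chromosome 17, 34198195 to 34201454) measured 12.05, 212.9 and 274.5 TPM in 6694c2 and 24.3, 173.9 and 308.6 TPM in 6419c5, changes of 4.27 (adjusted p 7.7e-09) and 3.11 (adjusted p 1.37e-06). H2-K1, a classical MHC class I gene (chromosome 17, 33996012 to 34000619), measured 376.7 ± 62.6, 2422 ± 437.1 and 2988 ± 192.4 TPM in 6694c2 (SD, n = 4 each), and 326.1 ± 54.0, 2085 ± 404.5 and 3904 ± 1839 TPM in 6419c5 (SD, n = 3 each). Iigp1, Gbp4, Psmb9, Ido1, Gbp2 and Chil4 rose by 3.66 to 4.01 in the mean. H2-Q8, Tgtp1 and Tgtp2 were also among the 12 largest, and they are uncertain because near-identical genes share their reads.

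Of 7 MHC class II genes, 7 were called higher in 6694c2 and 6 in 6419c5, or 3 in 6419c5 without its WT library 1. The list score in 6419c5 did not pass its exact permutation test (p 0.0714, adjusted 0.159). Camera called the list in both clones and for their difference, and with an estimated correlation in none of these (adjusted p 0.280, 0.961 and 0.893). Cd74 (chromosome 18, 60803849 to 60812652) measured 35.0 ± 9.60 TPM in WT, 689.5 ± 301.5 in KOA and 1525 ± 208.5 in KOB of 6694c2 (SD, n = 4 each), a change of 4.81 ± 0.44 (adjusted p 1.6e-07). In 6419c5 it measured 146.3 ± 60.5, 783.5 ± 462.0 and 919.1 ± 838.4 TPM (SD, n = 3 each), a change of 2.29 ± 0.50 (adjusted p 0.00131). The difference between the clones was 2.52 (adjusted p 0.00867). H2-Aa, H2-Ab1 and H2-Eb1 rose by 4.37, 4.44 and 4.73 in 6694c2 and by 1.72, 1.71 and 1.84 in 6419c5. The call of H2-Eb1 in 6419c5 (adjusted p 0.0154) was lost without WT library 1 (1.45, adjusted p 0.0934).

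In the interferon response list, 45 of 47 tested genes were called higher and 0 lower in 6694c2, the same counts adjusted over the list alone, with a median change of 1.55. In 6419c5, 43 were called higher and 0 lower, or 43 and 1 adjusted over the list alone, with a median of 1.66. The MHC class I list had 18 higher and 0 lower of 22 in 6694c2 (median 1.66), and 19 higher adjusted over the list alone. It had 17 higher and 1 lower in 6419c5 (median 1.55), or 18 and 1 adjusted over the list alone. The MHC class II list had 7 higher of 7 in 6694c2 (median 4.37) and 6 higher in 6419c5 (median 1.84), or 7 adjusted over the list alone. Leaving out 6419c5 WT library 1 reduced the 6 to 3. By line, the interferon response median was 1.44 in KOA and 1.88 in KOB of 6694c2, and 1.42 and 1.90 in 6419c5. The list scores of interferon response, MHC class I and MHC class II differed by 1.76, 1.96 and 4.03 in 6694c2, each higher in 8 of 8 KO libraries than in any WT library (exact permutation p 0.00202, adjusted 0.0117). In 6419c5 interferon response and MHC class I scores were higher in 6 of 6 KO libraries than in any WT library, by 1.78 and 1.63. Their exact permutation p of 0.0119 was the smallest that 3 against 6 libraries allow, and it did not pass after adjustment (0.0575). Other scores in 6419c5 had the same p. EPH receptors and ephrins (−0.34), TGF-beta genes (−0.51) and the pancreatic acinar list (−1.53) were lower in KO, and skin, fat and muscle was higher (0.39). MHC class II in 6419c5 had 5 of 6 KO libraries above WT (exact permutation p 0.0714). With the line as a random effect, interferon response genes called higher numbered 11 in 6694c2, 18 in 6419c5 and 34 for the mean.

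**Figure D3:**
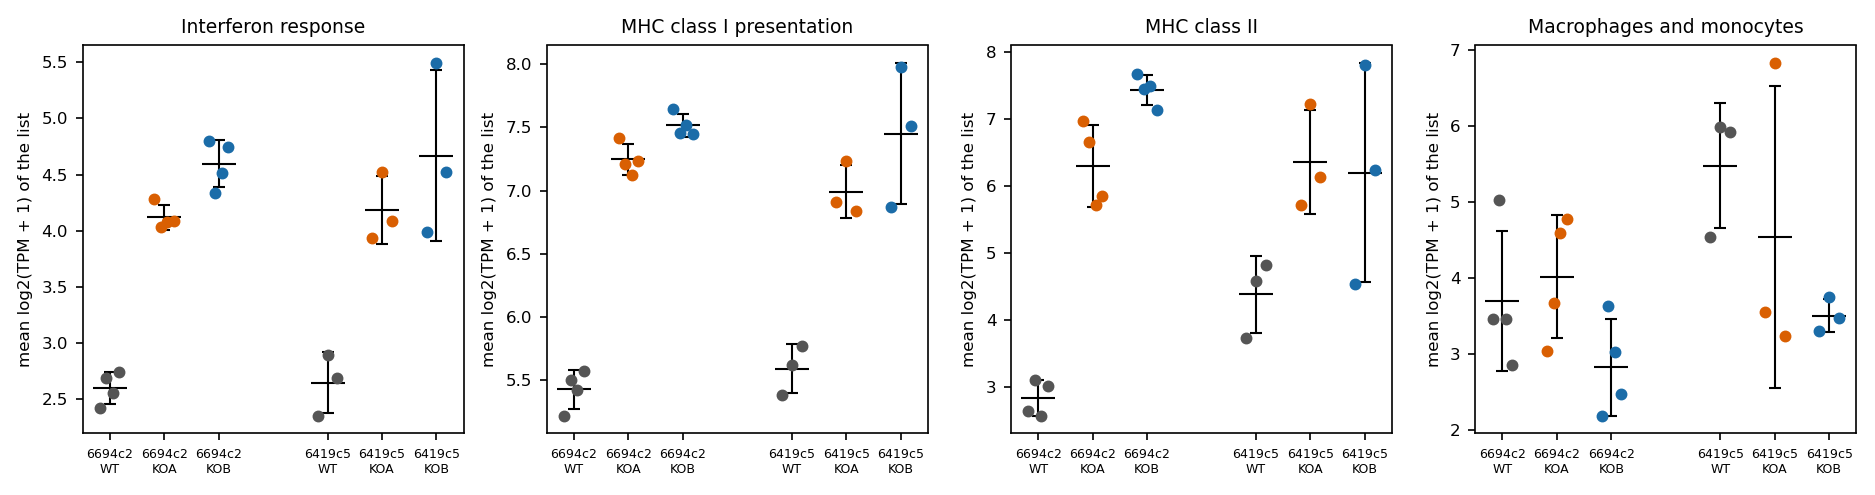
Mean log2(TPM + 1) of the members of 4 lists (interferon response, MHC class I, MHC class II, macrophages) in each library, by clone and line, with points for libraries and bars for the mean and SD. Every KO library lay above every WT library of its clone for interferon response and MHC class I, while macrophage scores of KO libraries lay below the lowest WT library in 2 of 8 and above the highest in 0 in 6694c2, and below in 5 of 6 and above in 1 in 6419c5.

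Camera with its preset correlation called 11 of 29 lists in 6694c2, 9 in 6419c5, 17 for the mean and 5 for the difference. With an estimated correlation it called 0 lists in all 4 contrasts, where the smallest adjusted p was 0.237 in 6694c2 and 0.106 in 6419c5. No call of a list by camera below therefore held with the estimated correlation. Higher lists in 6694c2 were interferon response, MHC class I and MHC class II. Lower lists there were cholesterol synthesis, mesenchymal genes, hypoxia and glycolysis, ERK pathway output, TGF-beta genes, cell cycle, immediate-early stress genes and the pancreatic acinar list. Of these, cholesterol synthesis and the acinar list were lower in both lines, with acinar medians of −0.83 in KOA and −0.99 in KOB. The others were lower in KOB, with medians of −1.24 for mesenchymal genes, −0.74 for hypoxia, −0.83 for ERK output, −0.51 for TGF-beta genes, −0.34 for cell cycle and −0.22 for immediate-early genes. In KOA their medians were 0.16, 0.15, 0.04, 0.03, −0.01 and 0.00, but libraries of KOA went opposite ways. ERK output scores were 6.01 and 5.73 in KOA libraries 1 and 2, below the WT range of 6.09 to 6.21, and 6.39 and 6.37 in libraries 3 and 4, above it. TGF-beta scores (5.01 and 4.94, then 5.46 and 5.44, WT 5.1 to 5.3) and immediate-early scores (6.98 and 6.70, then 7.45 and 7.49, WT 7.09 to 7.21) split in the same way. Hypoxia scores split the other way (7.70 and 7.79, then 7.42 and 7.42, WT 7.43 to 7.55). Mesenchymal scores were 5.06 and 4.61, then 5.45 and 5.54 (WT 5.06 to 5.13). Lists of other cell types moved along with these, with medians of 0.63 in KOA and −0.72 in KOB for fibroblasts and pericytes, and 0.37 and −0.87 for macrophages. The immediate-early call (adjusted p 0.0254) was lost without 6694c2 WT library 1 (0.0527) or KOB library 3 (0.0711), and passed in 34 of 40 alternatives. The acinar call passed in 33 of 39. Lists that did not pass in 6694c2 passed without 1 library in 3 cases. They were the macrophage list without WT library 4 (0.0384), ductal epithelium without KOA library 3 (0.0311) or 4 (0.0428), and the erythroid list without 6694c2 KOA library 2 (0.0408) or 6419c5 KOB library 1 (0.0413) or 2 (0.0361).

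Higher lists in 6419c5 were interferon response, MHC class I and MHC class II, and lower lists were TGF-beta genes, macrophages, fibroblasts, mesenchymal genes, EPH receptors and ephrins, and the acinar list. The MHC class II call (adjusted p 0.0302) was lost without WT library 1 (0.0523). The mesenchymal call (0.0324), with medians of −0.28 in KOA and 0.02 in KOB, was lost without WT library 3 (0.0899) or KOA library 2 (0.0539), and passed in 32 of 40 alternatives. Median-of-ratios size factors and quantile normalization each ended it, and each ended the fibroblast call (0.0242) too. The EPH call (0.0259) was lost with quantile normalization or no filter. Lists of NF-kappaB targets, ERK output, cholesterol synthesis, ductal epithelium and granulocytes had an adjusted p of 0.0501 and passed without some single libraries. These libraries were, for NF-kappaB targets, 6694c2 WT library 2, all 4 of 6694c2 KOA, and 6419c5 WT library 3, KOA library 3 and KOB library 1 (0.0217 to 0.0493). For ERK output they were 6694c2 WT library 2 and KOA library 3, and 6419c5 WT libraries 1 and 2 and KOB library 3 (0.0299 to 0.0493). For cholesterol synthesis they were 6694c2 WT library 2 and KOA libraries 1, 2 and 3, and 6419c5 WT library 3, KOA library 3 and KOB library 2 (0.00979 to 0.0493). For ductal epithelium they were 6694c2 WT library 2 and KOA libraries 1, 3 and 4, and 6419c5 WT libraries 1 and 2 and KOA library 2 (0.0276 to 0.0493). For granulocytes they were 6694c2 WT library 2 and KOA libraries 1, 2 and 3, and 6419c5 KOA library 2 and KOB library 3 (0.0338 to 0.0493). The prostanoid list passed without KOA library 2 (0.0421) and cell cycle without WT library 2 (0.0427).

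Cholesterol synthesis genes differed in direction between the clones. In 6694c2, 22 of 24 were called lower and 0 higher, or 23 and 0 adjusted over the list alone (median −0.70). In 6419c5, 12 were called higher and 2 lower, or 13 and 3 adjusted over the list alone (median 0.30). The medians by line were −0.46 in KOA and −0.85 in KOB of 6694c2, and 0.31 in both lines of 6419c5. Camera called the difference between the clones (median −0.96), as it did for MHC class II (2.52), hypoxia and glycolysis (−0.37), mesenchymal genes (−0.62) and macrophages (1.38). The mesenchymal call of the difference (adjusted p 0.039) was lost without 6694c2 WT library 1 (0.0583) or 3 (0.0519) or KOB library 2 (0.0548), and without 6419c5 WT library 1 (0.0835) or 2 (0.118), KOA library 1 (0.0776) or 3 (0.0622) or KOB library 1 (0.0567). The macrophage call of the difference (adjusted p 0.039) passed in 19 of 39 alternatives. It was lost without 6694c2 WT library 1, 3 or 4, KOA library 2, 3 or 4 or KOB library 2 or 4, and without 6419c5 WT library 2 or 3, KOA library 1 or 3 or KOB library 1 (0.0530 to 0.154). The interferon response did not pass for the difference (median 0.04, adjusted p 0.988), with 1 gene higher and 2 lower, or 6 lower without 6419c5 KOB library 1. MHC class I did not pass either (median 0.14, adjusted p 0.344), with 3 higher and 0 lower, or 6 higher without 6419c5 KOB library 2.

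**Figure D4:**
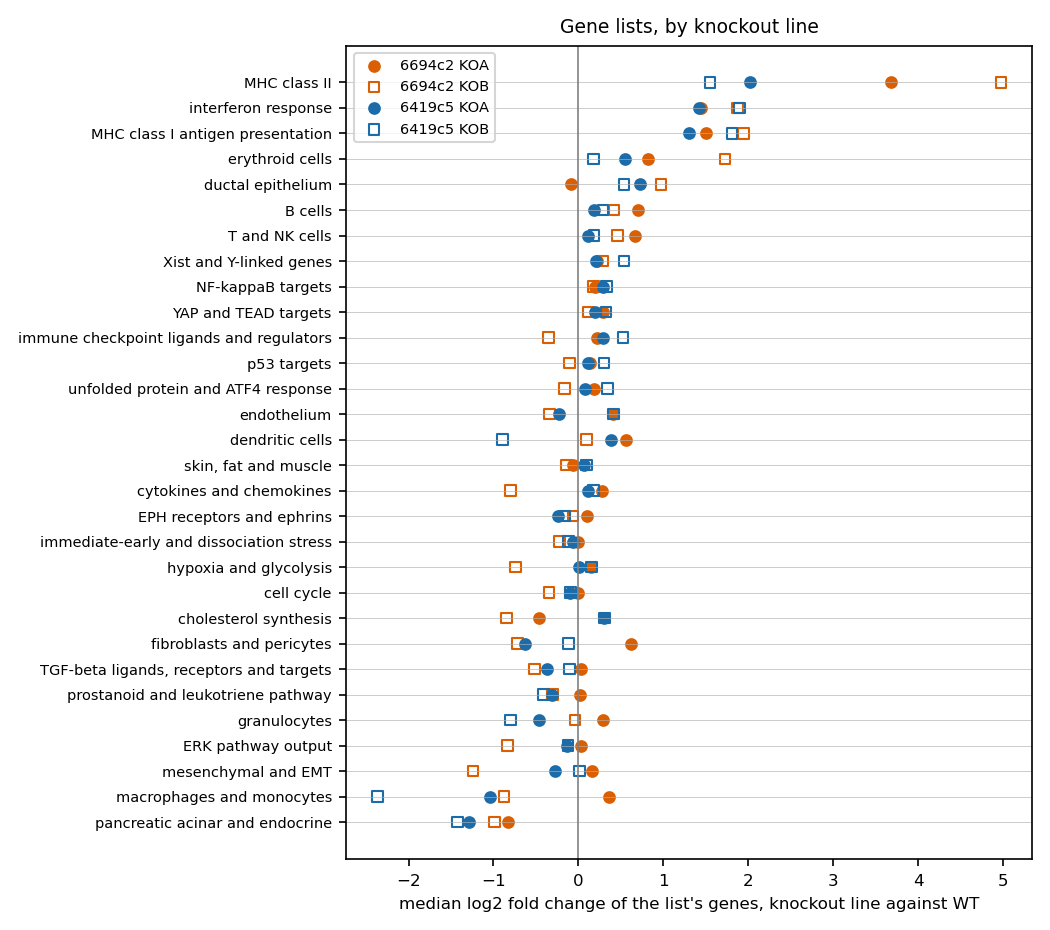
Median log2 fold change against WT of each list in each KO line, with filled circles for KOA, open squares for KOB, orange for 6694c2 and blue for 6419c5. Interferon response and MHC class I medians lay between 1.30 and 1.94 in all 4 lines, while mesenchymal genes ranged from −1.24 in KOB of 6694c2 to 0.16 in KOA of that clone.

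The other pathway lists are given as genes called higher and lower, in 6694c2 and then in 6419c5, with the counts adjusted over the list alone in parentheses. Of all 14337 tested genes, 37.4% were called in 6694c2 (3429 higher and 1932 lower) and 41.4% in 6419c5 (3796 and 2146). Counts near these shares do not set a list apart from other genes. EPH receptors and ephrins had 2 and 3 of 16 (2 and 3), then 1 and 6 (1 and 7). The prostanoid and leukotriene list had 6 and 6 of 21 (6 and 7), then 3 and 9 (5 and 10). TGF-beta ligands, receptors and targets had 4 and 16 of 31 (4 and 18), then 5 and 12 (5 and 13). Cytokines and chemokines had 7 and 10 of 36 (7 and 10), then 12 and 4 (12 and 4). Immune checkpoint genes had 9 and 5 of 25 (9 and 5), then 12 and 4 (13 and 5). NF-kappaB targets had 13 and 3 of 25 (13 and 3), then 12 and 1 (14 and 1). ERK pathway output had 1 and 11 of 22 (1 and 12), then 3 and 9 (3 and 9). YAP and TEAD targets had 9 and 3 of 20 (9 and 3), then 9 and 4 (9 and 5). Immediate-early and dissociation stress genes had 6 and 11 of 30 (6 and 11), then 3 and 7 (3 and 6). Cell cycle genes had 0 and 11 of 44 (0 and 8), then 4 and 5 (3 and 4). Hypoxia and glycolysis had 1 and 19 of 35 (1 and 22), then 7 and 7 (7 and 7). Unfolded protein and ATF4 genes had 7 and 4 of 29 (7 and 4), then 10 and 4 (10 and 4). P53 targets had 7 and 5 of 27 (7 and 5), then 10 and 3 (11 and 4). Ductal epithelium had 17 and 6 of 36 (18 and 6), then 20 and 5 (21 and 5). Mesenchymal genes had 0 and 18 of 29 (0 and 18), then 3 and 13 (5 and 13). Some of these counts moved when 1 library was left out. Cell cycle genes called lower in 6694c2 numbered 5 without WT library 3 or WT library 4 of that clone. In 6419c5, 10 cell cycle genes were lower and 6 mesenchymal genes higher without 6694c2 KOA library 2. Without 6419c5 WT library 1, 4 immediate-early genes were lower there. Without WT library 2, 5 prostanoid and 4 immediate-early genes were lower and 6 mesenchymal genes higher. Without WT library 3, 5 prostanoid, 1 cell cycle and 7 mesenchymal genes were lower and 2 TGF-beta genes higher. Without KOA library 2, 8 cytokine and 8 checkpoint genes were lower, and without KOB library 1, 5 immediate-early genes were higher.

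Lists that mark other cell types are given in the same way, to be read beside the same shares over all tested genes. Macrophages and monocytes had 1 and 0 of 29 (1 and 0), then 2 and 8 (2 and 8). The 8 lower genes in 6419c5 became 15 without WT library 1, 1 without WT library 2 or WT library 3, 2 without KOA library 1 or KOA library 3, 26 without KOA library 2 and 5 without KOB library 3. The median macrophage change there was −1.73. T and NK cells had 3 and 0 of 5 tested (4 and 0), then 0 and 0 (0 and 0). Granulocytes had 0 and 0 of 11 (0 and 0), then 2 and 5 (2 and 5), with 3 lower without 6419c5 WT library 2 or 3. B cells had 1 and 0 of 3 tested (1 and 0), then 0 and 0 (0 and 0). Dendritic cells had 3 and 1 of 11 (3 and 1), then 3 and 1 (3 and 2). Fibroblasts and pericytes had 3 and 2 of 22 (3 and 2), then 3 and 8 (4 and 10), with 5 higher in 6694c2 without KOA library 2. Endothelium had 1 and 0 of 15 (1 and 0), then 3 and 0 (3 and 0). Erythroid genes, whose hemoglobin members are uncertain because they share reads, had 5 and 0 of 6 (5 and 0), then 0 and 0 (0 and 0), with 3 higher in 6694c2 without WT library 4. Skin, fat and muscle had 1 and 2 of 12 (1 and 2), then 2 and 3 (5 and 3), with 5 higher in 6419c5 without WT library 2. The pancreatic acinar and endocrine list had 0 and 2 of 3 tested (0 and 2), then 0 and 3 (0 and 3). Xist, the only tested gene of its list, was not called in either clone, and no mitochondrially encoded gene was in the table. Exact permutation tests of the list scores in 6694c2 also passed for T and NK cells and the acinar list (p 0.00202, adjusted 0.0117), cholesterol synthesis (0.00404, adjusted 0.0195), erythroid genes (0.00808, adjusted 0.0335), and B cells and the skin, fat and muscle list (0.0121, adjusted 0.0391). Few markers of T and NK cells (5 of 31) and of B cells (3 of 14) passed the filter. Over all members in the table, without the filter, the exact permutation test in 6694c2 passed for 28 T and NK cell markers (0.26, 8 of 8 KO libraries above WT, adjusted p 0.0117), and not for 11 B cell markers (0.18, 7 of 8, adjusted p 0.143) or the skin, fat and muscle list (−0.09, 6 of 8 below WT, adjusted p 0.218).

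The sign of a list depended on the measure in some cases, none of which passed camera. In 6694c2, cytokines and chemokines had a median of −0.32 and a mean of 0.01, and fibroblasts had a median of −0.10 and a mean of 0.08. Immune checkpoint genes there had a median of −0.05, a mean of 0.23 and a direction of down in camera. EPH receptors and ephrins in 6694c2 had a median of 0.01 and a mean of −0.01. The ATF4, p53, granulocyte and endothelium lists in 6694c2 and the hypoxia list in 6419c5 had positive medians and means and a direction of down in camera, which compares a list with all other genes. Dendritic cells in 6419c5 had a median of −0.32, a mean of −0.08 and a direction of up. For the difference between the clones, median and mean differed in sign for TGF-beta genes (−0.03 and 0.21), interferon response (0.04 and −0.02), NF-kappaB targets (−0.28 and 0.01), ductal epithelium (−0.16 and 0.09) and immediate-early genes. Dendritic cells had a positive median and mean for the difference and a direction of down.

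Among decreases, Siglec15 had the largest decrease in the mean among well-identified genes, at −3.24 ± 0.16 (adjusted p 8.5e-11). It measured 146.0 TPM in WT, 99.7 in KOA and 2.69 in KOB of 6694c2, and 30.8, 0.869 and 3.2 TPM in 6419c5. Decreases in the mean of Mmp3, Nptx1, Cpn1, Grem1 and Dynap ran from −3.03 to −2.60. Rps27rt had a larger estimate and is uncertain, since near-identical genes share its reads. Mgp fell by 3.68 in 6694c2, where it measured 72.7 TPM in WT, 7.25 in KOA and 3.15 in KOB, and Mcpt8 fell by 3.44. Cck in 6694c2 measured 15.1 TPM in WT and 0.206 in KOA and was listed at 0 in KOB. Nptx1 fell by 5.04 ± 0.22 in 6419c5 (adjusted p 3.57e-11), from 45.8 TPM in WT to 0.512 in KOA and 0.207 in KOB.

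The difference of the KO effects asked which genes responded unequally in the clones. Limma called 4104 genes, 1864 with a higher and 2240 with a lower effect in 6694c2, and 39 with the line as a random effect. Tff2 had the largest difference, 7.31 ± 0.44 (adjusted p 8.83e-09). It measured 208.7 TPM in WT, 652.8 in KOA and 2912 in KOB of 6694c2, and 37.6, 0.846 and 0.389 TPM in 6419c5. Gkn2, Gkn1 and Tff1 had differences of 5.01, 4.95 and 4.15. Krt79 had the largest difference in the other direction, −5.30 ± 0.35 (adjusted p 2.05e-08). It measured 33.8, 31.8 and 9.04 TPM in 6694c2, and 6.80, 101.2 and 265.3 TPM in 6419c5. Krt14 followed the same direction (−3.27), with 1.74 TPM in WT, 36.1 in KOA and 50.6 in KOB of 6419c5.

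The KO lines of a clone were compared to see how far a KO effect was shared by both. In 6694c2, KOA against WT gave 3258 calls, 2174 higher and 1084 lower, and KOB against WT gave 6972 calls, 4185 higher and 2787 lower. With median-of-ratios size factors these splits were 1710 and 2107 for KOA, and 3646 and 3661 for KOB. KOA against KOB gave 6673 calls, 3288 higher and 3385 lower. The libraries of KOA in 6694c2 split on the second principal component, at 4.54 and 4.86 for libraries 1 and 2 and at 31.6 and 33.4 for libraries 3 and 4. KOA against WT had 2224 calls, 1226 higher and 998 lower, without libraries 3 and 4, and 4267 calls without libraries 1 and 2. In 6419c5, KOA against WT gave 4557 calls, 2738 higher and 1819 lower, and KOB against WT gave 6201 calls, 4088 higher and 2113 lower (3240 and 3353 with median-of-ratios size factors). KOA against KOB gave 2501 calls there, 683 higher and 1818 lower (1432 and 1413 with median-of-ratios size factors). That count was 1618 without 6419c5 KOA library 1 and 1557 without KOB library 2. Median-of-ratios size factors and quantile normalization each moved the median of all genes by −0.11 for KOB against WT in 6419c5. Quantile normalization moved it by −0.10 for KOA against WT in 6694c2.

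The effects of KOA and KOB against WT correlated across genes with r 0.439 and rho 0.321 in 6694c2 and with r 0.770 and rho 0.725 in 6419c5. Unchanged groups against the same WT libraries gave r 0.499 and 0.498 in simulation. Unchanged groups of equal size give about this r whatever the data, so it sets no bound for lines that changed. The covariance was 0.157 in 6694c2, against 0.0256 simulated, and 0.336 in 6419c5, against 0.0339. With the WT libraries of 6694c2 split 2 and 2, r was 0.376 and the covariance 0.141, so most of the covariance remained when the lines shared no WT library. Libraries on both sides of the split came from the same WT line. A difference particular to that line would remain in both effects, so the split does not show that the covariance belongs to the KO lines. Genes called in both lines of 6694c2 numbered 2144, of which 1194 were higher in both (635 from the counts alone), 578 lower in both (211) and 372 opposite. In 6419c5 they numbered 3373, of which 2141 were higher in both (781), 1180 lower in both (268) and 52 opposite. The counts in parentheses treat KOA and KOB as independent, but both were compared with the same WT libraries. Sharing WT libraries by itself favours calls in the same direction, so the excess does not measure a shared KO effect.

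The largest differences between the lines of 6694c2 were Gkn2 (−6.96 ± 0.51, adjusted p 7.44e-09), at 1.69 TPM in KOA and 327.5 in KOB, and Ifitm1 (5.28 ± 0.29, adjusted p 2.54e-10), at 246.0 and 5.04 TPM. Rhox5 measured 3.60 TPM in WT, 419.5 in KOA and 16.3 in KOB of that clone. In 6419c5 the largest among well-identified genes were Hoxb6 (−3.99 ± 0.22, adjusted p 1.49e-09), at 1.68 TPM in KOA and 40.5 in KOB, and Hmgn3 (3.46 ± 0.20, adjusted p 3.52e-09), at 27.2 and 1.58 TPM. Chromosome medians of KOA less KOB, after subtracting the median of all genes, reached 0.47 on chromosome X in 6694c2 and −0.33 on chromosome 18 in 6419c5. Those of the KO effect reached 0.25 on chromosome 10 in 6694c2 and −0.26 on chromosome 2 in 6419c5.

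**Figure D5:**
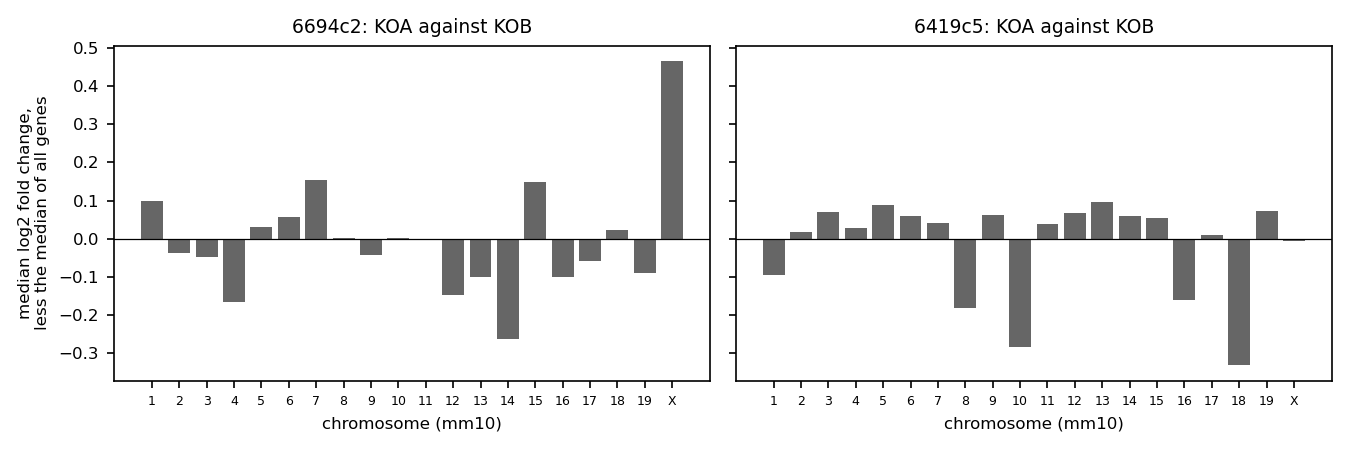
Median log2 fold change of KOA against KOB for the genes of each chromosome (mm10), less the median of all genes, as bars for 6694c2 and 6419c5. Chromosome X stood at 0.47 in 6694c2 and chromosome 18 at −0.33 in 6419c5.

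The WT lines of the clones were compared as a background for the KO effects. Limma called 7669 genes, 3079 higher and 4590 lower in 6694c2, or 4006 and 3915 with median-of-ratios size factors. Quantile normalization moved the median of all genes in this comparison by 0.11. Cdkn2b measured 0.245 TPM in 6694c2 and 211.0 in 6419c5 (−7.41 ± 0.11, adjusted p 2.2e-19). Rhox5 measured 3.60 and 1195 TPM (−8.04).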

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

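Tests of macrophage carry-over, of the scaling, of differences between single lines, of exchanged labels and of the edit were chosen only after the results they address were seen, while the chromosome tests and the splits of the samples were planned.

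Within groups of 4 libraries, which only 6694c2 has, 1 library stood apart from the other 3 by Dixon's test in 10 of 131 groups of values, and chance gives about 1 in 20. In WT library 2 the immune checkpoint score was 4.09 (3.73 to 3.77 in the others) and the dendritic cell score 2.19 (1.67 to 1.75). In WT library 1 the skin, fat and muscle score was 2.43 (2.12 to 2.17). In KOA library 2 the ATF4 score was 5.96 (6.16 to 6.19) and the skin, fat and muscle score 2.27 (1.97 to 2.005). In KOB library 4, Mir6236 took 14.5% of all TPM (2.27% to 2.68%), the hypoxia score was 6.84 (6.77 to 6.78) and Trp53 measured 131.5 TPM (192.6 to 196.6). Csf2 measured 3.27 TPM in KOB library 3 (4.47 to 4.55), and Csf3 measured 0.351 TPM in KOB library 1 (0.128 to 0.159).

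The KO effects of the clones differed by limma's test of the difference for 5 of the genes always named. The differences, 6694c2 less 6419c5, were −1.18 for Epha2, −1.20 for Ptgs2, −0.57 for Tgfb1, −1.41 for Csf3 and −0.57 for Myc. Camera with its preset correlation called the difference of 5 lists, with medians of 2.52 for MHC class II, −0.37 for hypoxia and glycolysis, −0.96 for cholesterol synthesis, −0.62 for mesenchymal genes and 1.38 for macrophages. None of the 5 lists passed with an estimated correlation.

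Other splits of the same libraries were run to see how often chance gives as much. Labels were permuted within clones in 100 splits, the real one included. For genes called, 1 of 100 splits gave as many, the real one, in each main contrast. The counts were 5361 in 6694c2 (highest other 3579), 5942 in 6419c5 (highest other 5280), 7010 for the mean (highest other 445) and 4104 for the difference (highest other 726). Single libraries were permuted and not whole lines, so the splits show mainly that libraries of a line resembled each other. They cannot tell a KO effect from chance differences between lines, since each clone has 1 WT line. For lists called by camera, 43 of 100 splits gave as many in 6694c2 (11, highest other 16), 51 of 100 in 6419c5 (9, highest other 15) and 84 of 100 for the difference (5, highest other 15), so chance is not excluded there. For the mean, 3 of 100 splits gave as many lists (17, highest other 19), and 2 of 100 gave as high a correlation between the clones (r 0.404, highest other 0.417). These shares were small, but another split exceeded the real value in both, and whole lines were not permuted. Chance is therefore not excluded for either.

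All 35 splits of 4 and 4 libraries were run for the lines of 6694c2 and all 35 of 4 and 3 for WT against WT. In each, 1 split gave as many genes, the real one, so grouping the libraries at random did not give as many calls. The splits do not show why the lines differed. The counts were 3258 for KOA against WT (highest other 1), 6972 for KOB against WT (highest other 2), 6673 for KOA against KOB (highest other 1625) and 7669 for WT against WT (highest other 4518). In 6419c5 the 10 splits of 3 and 3 are too few for a share under 0.05. The counts there were 4557 for KOA against WT (highest other 440), 6201 for KOB against WT (highest other 2) and 2501 for KOA against KOB (highest other 3).

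Interferon response and MHC genes were higher in the KO libraries of both clones, with interferon medians of 1.55 in 6694c2 and 1.66 in 6419c5, and in 6694c2 the scores of T and NK cells (0.61 over the 5 of 31 markers that passed the filter, and 0.26 over 28 without it, each with 8 of 8 KO libraries above WT) and erythroid cells (1.17, 7 of 8) rose with them, while the rise of B cells (0.54 over 3 of 14 markers, 8 of 8) did not pass without the filter (0.18 over 11, 7 of 8). For the interferon response, the tables argue against a larger amount of macrophages carried through the sort for tumour cells, which should remove them. Their 5 most abundant markers (Apoe, Lyz2, Cd14, C1qa and C1qc) moved by −0.50 on average in 6694c2 (95% upper bound 1.05) and by −1.54 in 6419c5 (upper bound 0.50), both bounds below the interferon median. Of the 5, Cd14 went the other way in 6419c5, where it was called higher by 0.64 (adjusted p 0.0021), less than the interferon median, and Lyz2 averaged 203.6 TPM in WT, 170.3 in KOA and 47.9 in KOB of 6694c2, and 816.8, 490.6 and 98.4 TPM in 6419c5. The bounds were set against the interferon median alone, and they took libraries of KOA and KOB as replicates. By line the macrophage list had medians of 0.37 in KOA and −0.87 in KOB of 6694c2, and −1.04 and −2.36 in 6419c5. Markers of amount do not measure the interferon genes of macrophages that were present, so that source stays open. In 6419c5 KOA the MHC class II score was highest in library 2 (7.23), as was the macrophage score (6.83). Libraries 1 and 3 had class II scores of 5.72 and 6.13 at macrophage scores of 3.56 and 3.24. KOB library 2 had a class II score of 7.81 at a macrophage score of 3.75. A part of macrophages in the MHC class II values of 6419c5, and in that list's difference between the clones, stays open. The tables also argue against the scaling of the values, since the lowest interferon median over 4 other scalings was 1.41 in 6694c2 and 1.57 in 6419c5. Carry-over of T and NK cells, B cells and erythroid cells was not tested and stays open. Differences between single lines unrelated to EPHA2 cannot be told apart from an effect of the knockout, because each clone has 1 WT line. Interferon response genes differed between the KO lines of a clone by a median of up to 0.58. Loss of EPHA2 may be the cause but stays untested against such differences.

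The KO lines of a clone differed in many genes, 6673 in 6694c2 and 2501 in 6419c5. Chromosome medians of the difference were spread more widely than in any of 1000 shuffles in both clones, and reached 0.47 on chromosome X in 6694c2 and −0.33 on chromosome 18 in 6419c5, so copy number differences between the lines may contribute. Medians of the KO effects against WT were spread more widely than in any of 1000 shuffles too (SD 0.112 against at most 0.0211 in 6694c2, and 0.102 against at most 0.0282 in 6419c5), and reached 0.25 on chromosome 10 and −0.26 on chromosome 2, so the same may hold for KO against WT. Between the KO lines, the 2 chromosomes beyond 0.25 held 8.66% of the calls in 6694c2 (6.37% of the genes) and 17.1% in 6419c5 (7.26% of the genes), so most calls lay elsewhere. Some chromosomes under that cutoff were one-sided too. In 6694c2, chromosome 7 had 385 calls higher and 131 lower in KOA, and chromosome 4 had 144 and 352. Others were even, such as chromosome 11 (255 and 252). The share on the 2 chromosomes therefore does not bound what copy number may contribute. DNA was not measured, and other differences between lines stay open.

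In 6419c5 the KO effect on Epha2 mRNA was not called, with all 3 KOA libraries below the lowest WT library (−0.22, adjusted p 0.173) and 2 of 3 KOB libraries above the highest (0.16, adjusted p 0.312). With the WT label of 6419c5 exchanged with KOA, r with the KO effect of 6694c2 was −0.22, and with KOB it was −0.31. As labelled it was 0.404 (jackknife SE 0.0523). KOA and KOB of 6419c5 moved together (r 0.770), so a positive r as labelled nearly fixes a negative r after an exchange. Chance is not excluded for the r as labelled, and it bears on the labels only if the knockout caused the shared change. An exchange of the WT label with a KO label therefore stays open. An edit that leaves the transcript in place stays open, since the whole-gene change of −0.034 holds no value over the edited exon and the labels do not give the edit. A KO line that kept EPHA2 cannot be excluded by these values either.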

How the results depend on the processing

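Leaving out chosen sets of libraries and rescaling without Mir6236 were chosen after seeing the data, and the other settings were fixed beforehand and all run. The Epha2 decrease in 6694c2 kept its direction and call in 40 of 40 alternatives (−1.30 to −1.12). Among 597 results of named genes, 0 of those called changed sign under any alternative, while Epha2 in 6419c5, which was not called, did. KO lines pooled ended the call of 74 of 573 such results and the line as a random effect of 337 of 573, since both count the spread between KO lines as error.

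Epha2 in 6419c5, not called, turned to 0.050 with the macrophage covariate (adjusted p 0.763) and to 0.023 without the libraries of high Mir6236 (adjusted p 0.903). Those libraries include 6419c5 WT library 3, so in 6419c5 this repeats the removal of that library. The adjusted p of Epha2 in 6419c5 by limma ran from 0.149 to 0.969 over the alternatives. With the line as a random effect, calls were 130 in 6694c2, 589 in 6419c5, 819 for the mean, 39 for the difference and 1328 for WT against WT, and 3 lists passed for the difference. Ptgs2 in 6419c5 lost its call with this fit, with KO lines pooled and with the macrophage covariate. The call was also lost without WT library 3 of 6419c5 and without the libraries of high Mir6236, which include that library. The Ptgs2 effect in 6419c5 ran from −0.98 to −0.51. With KO lines pooled, calls were 2858, 3690 and 1801 in 6694c2, 6419c5 and the difference. With arrayWeights, 8179 genes were called in 6694c2 and 6747 for its KOA against WT, r between the clones was 0.345 and r between the lines of 6694c2 was 0.255, and the cause was not tested. Each clone fitted alone gave 1350 calls for KOA against KOB in 6419c5, with fewer libraries behind the spread.

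With an estimated correlation camera called 0 lists in 6694c2, 0 in 6419c5, 0 for the mean and 0 for the difference. Fry called 16 lists in 6419c5 and 3 for the difference. A pseudocount of 5 gave 14 lists in 6419c5, and quantile normalization gave 2 for the difference. The exact test of list scores passed 0 lists in 6419c5 (9 at an unadjusted p under 0.05), and 7 with a pseudocount of 5, with median-of-ratios size factors and with quantile normalization. It passed 9 in 6694c2 and 5 with the filter at 5 TPM. Without 6694c2 KOA libraries 1 and 2, r between the lines of that clone was 0.205. Without libraries 3 and 4, it was 0.610, and 3 lists passed for the difference. The camera calls of the difference passed in 38 of 39 alternatives for MHC class II, 37 for hypoxia and glycolysis, 39 for cholesterol synthesis, 24 for mesenchymal genes and 19 for macrophages. The cause was not tested for these.

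When each library was left out in turn, calls ran from 4417 to 5661 in 6694c2, 5009 to 6300 in 6419c5, 6433 to 7291 for the mean and 3491 to 4417 for the difference. They ran from 2452 to 3926 for KOA and 6230 to 7286 for KOB against WT in 6694c2, from 3745 to 4901 and 5125 to 6521 in 6419c5, and from 6680 to 7964 for WT against WT. For KOA against KOB they ran from 5750 to 7063 in 6694c2 and 1557 (without 6419c5 KOB library 2) to 2844 in 6419c5. Epha2 in 6419c5 ran from −0.086 to 0.023. Lists passing ran from 10 to 12, 9 to 14, 13 to 17 and 3 to 5 for 6694c2, 6419c5, the mean and the difference. The correlation between the clones ran from 0.373 to 0.417, and between the lines from 0.347 to 0.512 in 6694c2 and 0.725 to 0.789 in 6419c5.

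A replicate block gave 4915, 5585, 6637 and 3601 calls for 6694c2, 6419c5, the mean and the difference. The library numbers showed no clear pairing of the groups, and the check is too small to exclude one in either clone. Over 21 pairs of libraries with equal numbers in different groups of a clone, residuals correlated at −0.147 to 0.173, 6 of them above 0.1, and the best match had the same number in 8. Depth could not be varied, since TPM keeps no counts.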

Other observations

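Mir6236 took 2.27% to 14.5% of all TPM per library, with 9.11% in 6419c5 WT library 3. Ribosomal protein genes took 14.2% to 21.6%. KOA libraries 3 and 4 of 6694c2 differed from libraries 1 and 2 in Csf2, at 44.5 and 45.5 TPM against 15.6 and 3.58, and in Cxcl1, at 123.8 and 129.6 against 30.3 and 8.75. In 6419c5 KOA, Lyz2 measured 1324 TPM in library 2 and 83.3 and 64.6 in libraries 1 and 3. No group or batch in the labels separates these libraries.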
